A study of Homo sapiens with 4 samples.

How the data were processed

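Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against TEAD4 was carried out in MKN28 and SNU216, 2 human gastric cancer cell lines. TEAD4 is a DNA-binding transcription factor of the TEAD family, which acts with the Hippo pathway co-activators YAP and TAZ. Each line gave 1 TEAD4 library and 1 input library of sonicated DNA without antibody. Per the labels' protocols, cells were cross-linked with formaldehyde, nuclei were sonicated, and the libraries were PCR-amplified, size-selected on a gel and sequenced on an Illumina Genome Analyzer.

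The submitters' processing notes name CASAVA 1.8, Bowtie2 2.0.0, MACS and the human genome build hg19. They give no settings for these tools, and the MACS version, read filters and duplicate handling are not given in the sources used here. The authors deposited 1 MACS peak list per TEAD4 library, called against the input of the same line as the names of the lists state, with no pooling of samples. Each list holds a position and the authors' score per peak, without a header, summit, read count or fold enrichment. The lowest score was 50.00 in MKN28 and 50.01 in SNU216 and a group of peaks sat at or just above 3100. This range fits the scale on which early MACS versions write a score, a multiple of −log10 of the p-value, but neither the lists nor the labels state it. Such a score rises with sequencing depth and with the depth of the input. Scores were therefore ranked and tested within 1 list in the main comparisons. Scores of the lists set side by side, score ratios of partner peaks included, describe these 2 libraries only. Sequencing depth is unknown, since the lists carry no counts. The input libraries were not analysed here as data of their own.

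Peak positions were converted to 1-based coordinates on hg19. Chromosome lengths and cytogenetic bands of hg19 came from the table bundled with circlize 0.4.16, and 0 peaks lay past the end of a chromosome. No hg19 gene annotation or genome sequence was used here, and coordinates were not moved to another build. Peaks were consequently not assigned to genes, and the comparisons of gene lists, gene positions and sequence motifs that had been planned were not run. Where a gene is mentioned with a band, it is textbook background on the band and not an assignment of a peak. The naming rule took the 10 highest-scoring peaks of each list that overlapped the other list and the 5 highest-scoring peaks of each list that did not. Ties were broken by the longer peak, and the part of the rule that asked for the nearest gene was left out.

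Overlap meant at least 1 shared bp. Shares of peaks carry exact 95% Clopper-Pearson intervals. The chance level came from 100 random placements of the SNU216 list with bedtools 2.31.1 shuffle, on the same chromosome and outside centromeric, variable and stalk bands. Peaks per chromosome were compared for chromosomes 1 to 22 and X as the SNU216 share of peaks divided by the MKN28 share. Its 95% interval came from 10000 bootstrap draws of 5 Mb blocks, because neighbouring peaks are not independent. Windows of 1 Mb were used for local density. For the closing section, each peak's width was divided by the median width of peaks of like score in the same list, in 50 groups by score rank, and summarised per window (at least 10 peaks in MKN28 and 5 in SNU216). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

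The code of the procedures was checked on simulated data. With a known part of the list planted on MKN28 peaks, the overlap step on 11540 peaks found 100% of the planted ones and 1.63% of the others. With no difference between lists, 93.0% of 460 chromosome intervals held 1, and a chromosome 20 ratio planted at 1.94 came back as 1.92. A stretch widened by 1.5 was recovered at 1.50 among 39477 peaks. The planted overlaps and the widening were fixed by construction. The lists with no difference were random draws of MKN28 peaks, without regional differences between lists. These checks therefore test the code and not how the intervals behave on the real lists.

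With 1 library per line, no difference between the lines has a replicate check. The main comparisons carry no p-value, and the permutation p-values over chromosomes in the closing section describe these 2 libraries. Intervals cover counting error or the scatter along the genome, not the spread between cultures or immunoprecipitations. Alternatives to the overlap rule, the score threshold, the list length and the random placement were fixed before the data were examined. The naming rule was fixed then as well. Other alternatives were added later, and the closing section names them. Not all comparisons in the Results are claimed to have been fixed beforehand. No such claim is made for the bootstrap intervals per chromosome, the groups by score or the sets of strongest peaks. The same holds for the densest windows, the extreme blocks and the score correlation of partner peaks.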

Results

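TEAD4 binding was profiled by ChIP-seq in 2 gastric cancer cell lines, MKN28 and SNU216, to map the sites that this transcription factor occupies across the genome. The data are 1 peak list per line, each from 1 TEAD4 library called by the authors against 1 input library of the same line. No group held replicates. The design implies a description of each list and a comparison of the lists, and the intervals below cover counting error or scatter along the genome only. Depth is unknown because the lists hold no read counts.

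TEAD4 peaks were called at 39477 sites in MKN28 and at 11540 sites in SNU216, a ratio of 3.42. The MKN28 peaks covered 22.3 Mb, or 0.721% of hg19, and the SNU216 peaks covered 5.17 Mb, or 0.167%. MKN28 peaks were wider, with a median of 525 bp (quartiles 422 and 652 bp) against 408 bp (332 and 514 bp) in SNU216. The median distance between neighbouring peak midpoints was 26.5 kb in MKN28 and 80.4 kb in SNU216. The median score given by the authors' peak caller was 99.8 in MKN28 and 84.7 in SNU216. A score of at least 100 was reached by 19685 MKN28 peaks (49.9%) and 4866 SNU216 peaks (42.2%). A score of 3100 or more, where the values pile up, was reached by 16 MKN28 peaks and 1 SNU216 peak. The 2 lists can differ in length through sequencing depth or enrichment as well as through occupancy. Why the peaks of the 2 lists differed in width was not tested.

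Many TEAD4 sites of SNU216 were also called in MKN28. Of the 11540 SNU216 peaks, 6841 (59.3%, 95% interval 58.4 to 60.2) overlapped an MKN28 peak, and 4699 did not. The share was 48.2% when 50% of both peaks had to overlap. In the other direction, 6752 of the 39477 MKN28 peaks (17.1%, 16.7 to 17.5) overlapped an SNU216 peak, and 32725 did not. Random placement of the SNU216 peaks on their own chromosomes gave an overlap of 1.55% ± 0.114 (SD over 100 placements), with a highest value of 1.77%. The observed overlap was 38.4 times that level. This fold was 18.5 against the same peaks shifted by 20 kb, where 3.20% still overlapped. Among peaks with a score of at least 100 it was 74.4, with 68.7% overlapping against a random level of 0.923%. That higher fold came mostly from the lower random level, since the observed share rose only from 59.3%. When MKN28 was limited to its 11540 highest-scoring peaks, 36.1% of SNU216 peaks overlapped them, so the share depended on the length of the MKN28 list.

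The overlap rose with peak score in both lists. Its level is not comparable between the full lists, since SNU216 peaks were matched against a list 3.42 times as long. Each list was divided by score into 10 groups of equal size. In the highest-scoring SNU216 group (score 304 and above), 91.3% (89.6 to 92.9) overlapped an MKN28 peak, against 29.03% (26.4 to 31.7) in the lowest-scoring group. In the highest-scoring MKN28 group (score 422 and above), 50.2% (48.6 to 51.8) overlapped an SNU216 peak, against 4.46% (3.84 to 5.15) in the lowest-scoring group. Of the 100 strongest SNU216 peaks, 96 overlapped an MKN28 peak (90.1 to 98.9%). Of the 100 strongest MKN28 peaks, 81 overlapped an SNU216 peak (71.9 to 88.2%). Among the 500 strongest, the counts were 481 in SNU216 and 363 in MKN28. Against an MKN28 list of equal length, a setting added after seeing the data, 88 of the 100 strongest SNU216 peaks overlapped (80.0 to 93.6%), an interval that shares values with that of the 81 MKN28 peaks. Of the 500 strongest, 440 SNU216 peaks then overlapped (88.0%, 84.8 to 90.7), against 72.6% (68.5 to 76.5) of the MKN28 peaks. The share fell at each step down through the 10 groups in both full lists.

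**Figure D1:**
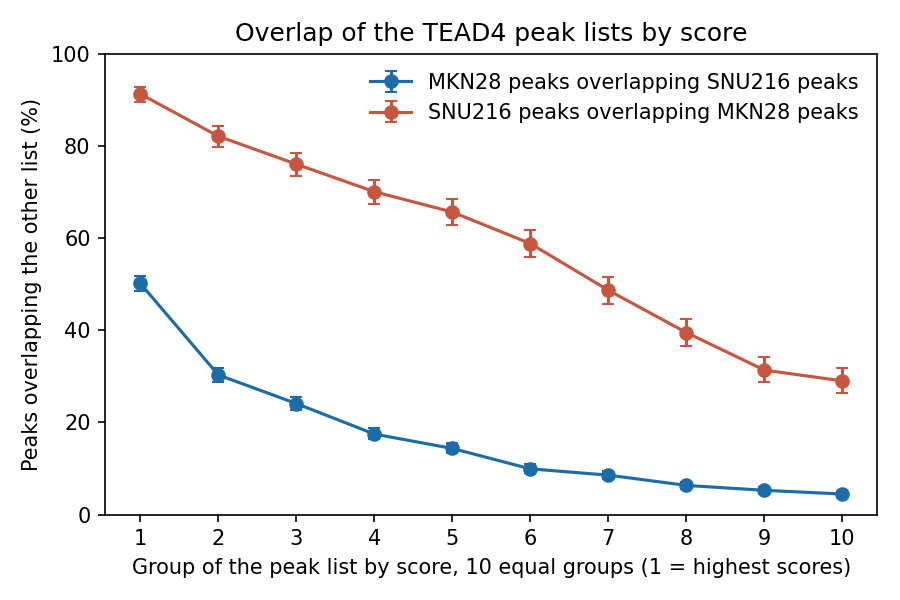
Share of peaks overlapping the other line's list (y axis, percent) for 10 groups of equal size of the MKN28 and SNU216 lists ordered by score (x axis, 1 is the highest-scoring group). Points are shares and bars are exact 95% binomial intervals; the lists searched differ in length, and SNU216 falls from 91.3% to 29.03% and MKN28 from 50.2% to 4.46%.

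Sites occupied in both lines were the stronger and wider ones within each list. In MKN28, the median score was 226 (quartiles 114 and 491) for overlapping peaks and 88.6 (62.5 and 159) for the others, a ratio of 2.55. In SNU216, the medians were 115 (72.2 and 217) and 64.8 (55.8 and 90.8), a ratio of 1.77. The median widths of overlapping and other peaks were 618 and 508 bp in MKN28 and 444 and 360 bp in SNU216. A score of at least 1000 was reached by 797 MKN28 peaks, of which 255 had no counterpart, and by 86 SNU216 peaks, of which 3 had none. These counts are not comparable between the lines. The same score takes unlike parts of the 2 lists, and the SNU216 peaks were matched against a list 3.42 times as long. Across the 6841 overlapping SNU216 peaks, the score followed that of the best MKN28 partner with a Spearman rho of 0.38. That correlation is across peaks, which are not independent replicates.

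The strongest sites common to both lines lay in separate places on many chromosomes, and 2 regions were among the 10 strongest overlapping peaks of both lists. The first was on chromosome 3 (134045581 to 134046205 in SNU216, band 3q22.2). It had the highest score of the SNU216 list, 3117, and its MKN28 counterpart, at 134045465 to 134047455, scored 3100. The second was on chromosome 1 in band 1p22.3, at 86072491 to 86073419 with a score of 1928 in SNU216 and at 86072401 to 86074038 with a score of 3100 in MKN28. The second strongest SNU216 peak, in 1p36.13 (chromosome 1, 19378722 to 19379500), scored 2928 and its MKN28 partner scored 3100. Several MKN28 peaks were tied at 3100, where the values pile up. That partner missed the 10 strongest only through the tie-break on width, at 878 bp against 899 bp for the last peak taken. The count of 2 regions therefore depends on the tie-break. Because the values pile up there, the order of scores at or just above 3100 cannot be read as an order of strength. The highest score of the MKN28 list, 3170, was in 8q24.21 (chromosome 8, 128821303 to 128823068), the band that holds the MYC oncogene. The SNU216 peak inside that interval scored 373. An SNU216 peak in 11q13.3, the band of the cyclin D1 gene CCND1, scored 1960 (chromosome 11, 69235267 to 69235774) and its MKN28 partner scored 2706. The other named SNU216 peaks were in 20q13.33, 3q29, 15q22.2, 7q36.3, 6q25.3 and 10p11.22. The MKN28 partners of the 10 strongest overlapping SNU216 peaks scored from 174 to 3100. The SNU216 partners of the 10 strongest overlapping MKN28 peaks scored from 84.3 to 3117, with a median of 848.

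Some of the strongest MKN28 sites had no SNU216 peak. The 5 strongest of these were in 22q11.21 (chromosome 22, 21391606 to 21392843, score 3100), 1p36.31 (chromosome 1, 5464283 to 5465404, score 3100), 11q23.3 (score 2985), 19q13.12 (score 2766) and 8q24.21 (chromosome 8, 128831431 to 128833409, score 2575). The 5 strongest SNU216 peaks without an MKN28 peak scored lower within their own list. They were in 8q22.3 (chromosome 8, 104992168 to 104993344, score 1183), 2q11.1 (score 1104), 3q26.2 (score 1011), 5q13.2 (score 999.8) and 1q21.3 (score 758). A site missing from a list was below the authors' threshold there, which does not show that TEAD4 was absent. The 22q11.21 peak lay in the 1 Mb window where MKN28 peaks were the widest for their score, and 2q11.1 is a centromere band. The 1p36.31 peak lay in a stretch of chromosome 1 (3000001 to 6000000) where MKN28 peaks were 1.35 times as wide for their score and 1 of 70 overlapped an SNU216 peak. Peaks from 120 to 132 Mb of chromosome 8, across 8q24, were 1.36 times as wide in MKN28 and 1.24 times as wide in SNU216 as peaks of like score in the same list.

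TEAD4 peaks were spread unevenly over the genome, and the densest windows were partly common to both lines. MKN28 had up to 66 peaks in 1 Mb, in a window on chromosome 1 (94 to 95 Mb, bands 1p22.1 to 1p21.3) where SNU216 had 19. SNU216 had up to 34 peaks in 1 Mb, in 6p22.2 on chromosome 6 (26 to 27 Mb), where MKN28 had 42 and 24 of the SNU216 peaks overlapped an MKN28 peak. The next window, in 6p22.1, held 29 SNU216 and 54 MKN28 peaks, and these bands carry the largest cluster of histone genes. A window in 11q13.1 to 11q13.2 (chromosome 11, 65 to 66 Mb) was among the 5 densest of both lists, with 58 MKN28 and 27 SNU216 peaks. The window of 11q13.3 held 26 SNU216 and 51 MKN28 peaks. Over 100 random placements, the fullest window held at most 53 MKN28 or 21 SNU216 peaks. Gaps in the mappable sequence other than the excluded bands were not modelled in these placements.

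The 2 lines differed in how their peaks were divided among chromosomes. SNU216 had a larger share of its peaks than MKN28 on chromosome 14 (ratio of shares 1.52, 95% interval 1.29 to 1.82), chromosome 3 (1.496, 1.33 to 1.69) and chromosome 20 (1.39, 1.21 to 1.67). Smaller excesses were found on chromosomes 8 (1.204, 1.03 to 1.36) and 6 (1.19, 1.06 to 1.34). SNU216 had a smaller share on chromosomes 22 (0.615, 0.468 to 0.758), 13 (0.623, 0.512 to 0.766), X (0.667, 0.498 to 0.842) and 12 (0.673, 0.598 to 0.751). It was also smaller on chromosomes 2 (0.714, 0.635 to 0.789), 19 (0.747, 0.620 to 0.906) and 15 (0.871, 0.744 to 0.987). With a score of at least 100 in both lists, the intervals of chromosomes 19 (0.793, 0.579 to 1.08) and 15 (0.914, 0.726 to 1.12) held 1. Without windows of wide peaks, a setting added later, the intervals of chromosomes 8 (1.13, 0.914 to 1.38) and 15 held 1. With all peaks, the intervals of the other 11 of the 23 chromosomes held 1. On chromosome 20, SNU216 had 522 peaks and MKN28 1285, and on chromosome 22 they had 167 and 929. Peaks in 20q11.21 to 20q11.23 were 1.31 times as wide in SNU216 and 1.13 times as wide in MKN28 as peaks of like score in the same list. These intervals describe scatter along the genome in 1 library per line, and are not adjusted for the 23 chromosomes.

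**Figure D2:**
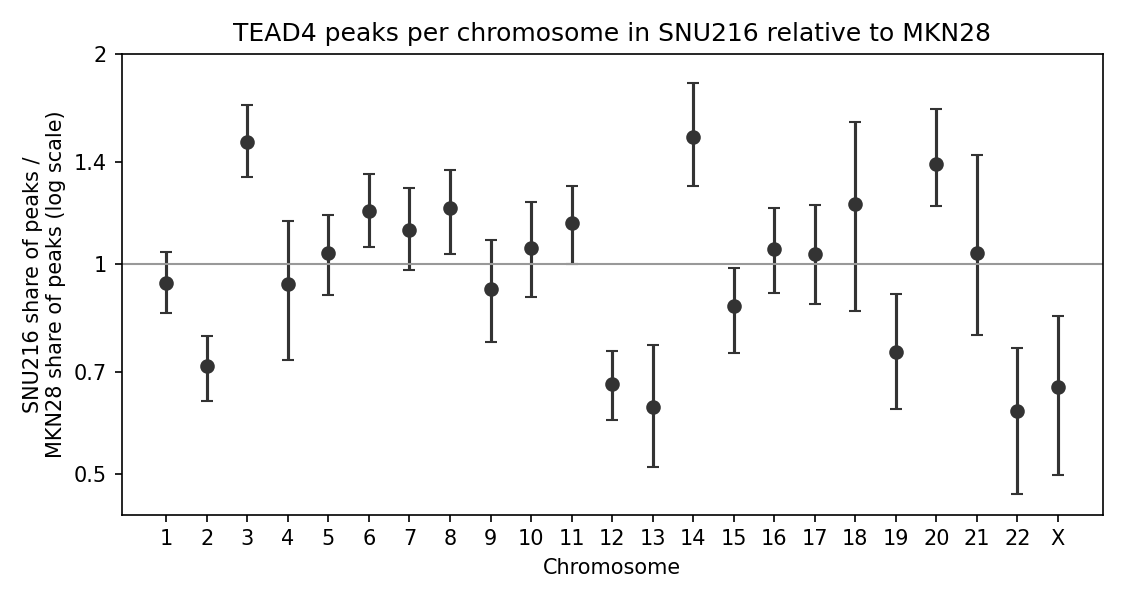
SNU216 share of peaks divided by MKN28 share of peaks (y axis, log scale) for chromosomes 1 to 22 and X (x axis). Points are ratios, bars are 95% intervals from 10000 bootstrap draws of 5 Mb blocks, and the line marks 1; chromosome 14 is highest at 1.52 and chromosome 22 lowest at 0.615.

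Within chromosomes, some blocks held called peaks almost only in MKN28, the longer list. Over all chromosomes compared, 22.6% of the peaks of both lists together were SNU216 peaks. Of 518 blocks of 5 Mb with at least 30 peaks in total, 63 had an interval above that share and 70 an interval below it. These binomial intervals treat peaks as independent, which neighbouring peaks are not, and even then up to 26 of the 518 would fall outside by chance. The lowest was chromosome 4 from 180 to 185 Mb (4q34.3 to 4q35.1), with 53 MKN28 peaks and 1 SNU216 peak. The block beside it, up to 190 Mb, held 86 MKN28 and 3 SNU216 peaks. A block in 15q11.2 to 15q13.1 held 67 and 2, and one in 2p24.3 to 2p24.1 held 77 and 3. The highest SNU216 share, 60.6% (42.1 to 77.1), was in the last part of 4q35.2, with 20 SNU216 and 13 MKN28 peaks. The blocks that followed were in 14q32.33 (20 and 15 peaks), 7q21.11 (26 and 22), 3q11.2 to 3q12.1 (23 and 20) and 20q13.33 (37 and 34). The blocks of 4q35.2, 14q32.33 and 20q13.33 reach the chromosome end.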

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

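With a score of at least 100 in both lists, 19685 MKN28 and 4866 SNU216 peaks remained, 68.7% of SNU216 peaks overlapped an MKN28 peak, and the fold over random placement was 74.4. The share of SNU216 peaks overlapping an MKN28 peak was 48.2% when 50% of both peaks had to overlap, 54.6% for midpoints within 200 bp, and 36.1% against an MKN28 list of equal length. The share of MKN28 peaks overlapping an SNU216 peak was 14.1%, 16.0% and 35.2% under the same settings. The fold was 31.6 with the SNU216 peaks shifted by 1 Mb and, in a setting added after seeing the data, 18.5 with a shift of 20 kb, where 3.20% still overlapped. The stricter overlap changed the ratio of median scores of shared to other peaks to 2.31 in MKN28 and 1.89 in SNU216. Lower overlap shares under the rules that ask for more overlap follow from their construction, as does the lower SNU216 share against a shortened MKN28 list. The 35.2% is the share of the 11540 highest-scoring MKN28 peaks, and overlap rose with score. The fold at a score of at least 100 rose mostly through its lower random level, 0.923% against 1.55% for all peaks. The cause of the remaining moves was not tested. Leaving out windows of wide peaks, or peaks within 1 Mb of centromere bands or chromosome ends (both added later), kept both shares within their intervals. The 36 ratios of shares recomputed for the 12 named chromosomes, under 3 added settings, stayed within their main intervals and on their side of 1. The number of chromosomes with an interval above 1 was 5 to 6, and below 1 it was 5 to 7. Chromosomes 19 and 15 were lost at a score of at least 100, where fewer peaks remained. Their intervals were wider (19: 0.620 to 0.906 became 0.579 to 1.08). Their ratios also moved toward 1, from 0.747 to 0.793 on chromosome 19 and from 0.871 to 0.914 on chromosome 15. Chromosome 15 was also lost with lists of equal length (0.754 to 1.004) and, with chromosome 8 (1.13, 0.914 to 1.38), without windows of wide peaks. The number below 1 was still 7 with lists of equal length, and the number above 1 was still 5 without windows of wide peaks. Chromosomes outside the 12 named thus entered in those settings, and the counts hide this turnover. Settings that need genes, starts or motifs were not run. No replicate could be left out, since each line has 1 library. No paired analysis was possible because each group holds 1 library and the labels give no replicate numbers. Unknown depth limits every statement on peaks found in 1 list.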

Other observations

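All tests in this part were chosen after the results they bear on were seen, or after the patterns were noticed.

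Regions where many neighbouring peaks were wide for their score stood out in both lines. In MKN28, peaks in 22q11.21 (chromosome 22, 21 to 22 Mb) were 2.52 times as wide as MKN28 peaks of like score, with a median of 1365 bp over 47 peaks, of which 1 overlapped an SNU216 peak. Peaks across 8q24 (chromosome 8, 120 to 132 Mb) were 1.36 times as wide in MKN28 (299 peaks) and 1.24 times as wide in SNU216 (127 peaks). In SNU216, wide peaks ran over 17q12 to 17q21.2 (chromosome 17, 36 to 39 Mb), the region of the receptor tyrosine kinase gene ERBB2, at 1.36 times (55 peaks). They also ran over 4 stretches of chromosome 20, the longest from 30 to 36 Mb (20q11.21 to 20q11.23) at 1.31 times (64 peaks). The widest SNU216 windows of all were beside centromeres, at 4p11 (3.53 times, 12 peaks), 1q12 to 1q21.1 (2.84 times, 12 peaks) and 21p11.2 to 21p11.1 (2.41 times, 10 peaks), with median scores of 86.7, 67.9 and 71.3. MKN28 peaks in those 3 windows were wide as well, at 2.13, 1.88 and 1.52 times on 6, 8 and 5 peaks. Within centromere bands and 1 Mb around them, 44.5% of 265 SNU216 peaks and 16.8% of 702 MKN28 peaks overlapped the other list.

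The stretches of wide peaks may reflect DNA copy number, local signal or broad binding regions. The 13 found count 8q24 from each list separately. In 2 of the 13 the other line's interval lay above 1.2, and in 5 it held 1.2. Those 2 were SNU216 stretches in 8q24.12 to 8q24.13 (SNU216 fold 1.29, MKN28 fold 1.32) and in 8q24.21 (1.30 and 1.36). Wide peaks in 8q24 were thus found from either list. In the other 6, the other line's interval lay below 1.2 and below the line's own. They are 9p13 (SNU216 fold 0.930, 11 peaks), 17q12 to 17q21.2 (MKN28 fold 0.979), 20q11.21 to 20q11.23 (MKN28 fold 1.13, 1.09 to 1.17), 2 more of the 4 on chromosome 20 and 1 in 1p36 that rests on 3 SNU216 peaks. Each stretch was picked because its own line's windows reached 1.2, so a lower fold in the other line is likely from that choice alone. The intervals also treat neighbouring peaks as independent. These 6 therefore cannot decide on a region broad in both lines. In 9p13 and 17q12 to 17q21.2, the other line's peaks were about as wide as its peaks of like score. In 8q24 the SNU216 fold was 1.24 (95% bootstrap interval 1.18 to 1.31), and the MKN28 folds in the 4 stretches of chromosome 20 (1.09 to 1.15) also had intervals above 1. Whether a gain lay in 1 line alone cannot be told apart there. Of 624 SNU216 stretches of that length elsewhere, 36, all on chromosomes 8 and 20, were as wide as 8q24. Of 1164 MKN28 stretches, 99 were as wide as 20q11.21 to 20q11.23. These stretches were taken in steps of 1 Mb and overlap one another, so the counts stand for fewer separate regions. Wide windows lay together. The longest run in MKN28 was 6 windows of 1 Mb, against at most 3 in 100 permutations, and in SNU216 it was 6 against at most 4. Of the 6 stretches listed above, all but 20q11.21 to 20q11.23 were no longer than such permuted runs. Regional gain of DNA copies and a broad region bound in only 1 line cannot be told apart by this. Either could give such runs, that a gain widens peaks was not tested, and the input libraries were not analysed here.

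Strong MKN28 peaks without an SNU216 peak could be line-specific sites or a matter of scale. Among the 500 strongest MKN28 peaks, 137 had no partner, and the SNU216 partners of the other 363 had a median score ratio of 0.254 with an SD of 1.29 on the log2 scale and 44 scores under 100, known only where a partner was called. Scaled by that median ratio, the 137 would score 311 to 788, with 0 below the list floor of 50. That scaling ignores the scatter, and the ratio leaves out peaks whose partner fell below the threshold. With lists of equal length, 81% of the 100 strongest MKN28 peaks overlapped against 88% of the SNU216 peaks, 72.6% (68.5 to 76.5) against 88.0% (84.8 to 90.7) of the 500 strongest, and 64.5% (61.4 to 67.5) against 81.3% (78.7 to 83.7) of the 1000 strongest. The intervals of the larger sets do not meet, but a common scaling with scatter and a detection limit cannot be told apart from site-specific differences, since 1 library per line leaves the scatter of a score between libraries unknown. Of the 137, 11.7% (6.82 to 18.3) lay in windows of wide MKN28 peaks, against 10.2% of the 363 (129 of the 137 were in windows with enough peaks to test), which leaves regional gain open because no test shows that a gain widens peaks.

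The unequal division of peaks among chromosomes may follow copy number differences between the lines, and 2 relations were computed over the 23 chromosomes. The log2 ratio of shares rose with the difference in peak width for like score, the direction expected if extra copies widen peaks, which was not tested (Pearson r = 0.59, permutation p = 0.0026; Spearman rho = 0.63, permutation p = 0.0016, both unchanged by Benjamini-Hochberg adjustment; r = 0.58 without chromosomes 15 and 20). It also rose with the score ratio of shared peaks (r = 0.75, p = 6e-05, adjusted 0.00012; rho = 0.85, p = 1e-05, the smallest these permutations can give, adjusted 2e-05; r = 0.75 without chromosomes 2 and 18). With a fixed score floor, scores and numbers of peaks read the same signal, so the second relation is what any cause would give and does not speak for copy number. Copy number and a chromosome-wide difference in chromatin or TEAD4 occupancy both stay open.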
